A study of Mus musculus with 6 samples.

How the data were processed

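Expression was profiled in cells sorted for EGFP from the main olfactory epithelium of E18.5 mouse embryos, heterozygous or null for Fezf1, with 3 arrays per genotype. RNA was extracted with a Qiagen micro kit and 100 ng of total RNA was labelled with biotin, per the labels' protocols. The arrays were Affymetrix Mouse Gene 1.0 ST arrays, per the series' design text. Groups and replicate numbers came from the genotype and the title of each sample.

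The deposited values are log2 signals per probe set and array, which the authors made with GCRMA and Affymetrix Expression Console, per the submitters' processing notes. Those notes, as used here, give neither the order nor the versions of these programs, and any filter or batch correction is not given in the sources used here. The log base is not stated either: it was taken as 2 because the values run from 2.14 to 14.5, and a natural logarithm of a 16-bit scanner reading cannot exceed 11.1. Scanner files were not used here, so background and saturation could not be examined per probe. Quantiles of the 6 arrays were close to each other, with medians from 5.82 to 5.95, and the values were used without further normalisation. GCRMA subtracts an estimated background, so differences between 2 values near the bottom of the range are compressed or set by that estimate. Fold changes are ratios of these signals and do not measure molecules. For arrays, precision is limited by their number, 3 per group.

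Of 35557 probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 12147 were not listed there. That annotation dates from 2016 and can be old, so symbols were updated through the Entrez number to RefSeq gene names of GRCm38.p6, which matched for 21698 probe sets. The same table served to find neighbouring genes and gave no coordinates, because the sources used here name no genome build. Each gene was represented by its probe set with the highest mean over all 6 arrays, which ignores the groups, and 999 genes had more than 1 probe set. This left 19938 genes, with no filter on low values. Odorant and vomeronasal receptors are large families of similar genes, so a probe set of one receptor may also bind transcripts of another, and single receptor values are uncertain to that extent.

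Null and heterozygous arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and a second count asked for a difference of at least 2-fold. Every adjusted p of a gene is from limma. The p-values measure the spread between these samples, and the labels do not say whether replicates were separate embryos, litters or pools. Exact comparison of 3 against 3 single values cannot give a p below 0.1, so no such test was run. A set of 36 gene lists covered neuron classes, receptor families, progenitors, supporting cells, cell types that a sort could carry, cilia, axon guidance, synapse, stress and housekeeping genes. The 35 lists with at least 3 measured members were tested against all other genes with limma's camera at its preset correlation of 0.01, and again with the correlation estimated from the data. The fry test asked whether the genes of a list moved in the same direction, and its mixed form whether they changed in either direction. Some genes stand in 2 lists, such as Kirrel2, Cbr2 and Sox10.

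The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were Fezf1 and Fezf2, the 15 largest rises and 15 largest falls among genes past the threshold whose null values all lay on one side of the heterozygous values, and from each list up to 4 members past the threshold by size of change, or the 2 with the smallest p where none passed. Null replicate 1 differed from the other arrays, so the fit without it, planned as one of the fits that leave out an array, is given beside the result from all 6. The counts per list and the named genes of that fit were added after seeing the data, and so were genes named outside the rule, among them Omp, Adcy3, Cnga2, Gnal, Ms4a6c and Col1a1.

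Alternatives were quantile normalisation, centring of each array on its median, a filter on genes above the median mean, averaging of probe sets, a floor of 4 on the linear scale (which lay below every value), eBayes with trend and robust settings, array weights, an unmoderated per-gene test, the replicate number as a block, and leaving out each array in turn. The procedure was tested on simulated data in which 200 of 19938 genes were changed. With 3 null and 3 heterozygous arrays it recovered 68% of 2-fold and 86% of 4-fold changes in 157 calls, of which 3 were false. With 2 null arrays, without null replicate 1, it recovered 96% of 2-fold and 100% of 4-fold changes in 209 calls, of which 13 were false. The simulated noise was normal, independent between genes and of the same spread on every array. It held no array that stood apart and no compression near background. These rates therefore describe the procedure under such noise and are not the error rates of these data.

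Closing tests drew 10000 random lists of genes matched on mean signal or 10000 permutations, each with a fixed seed, and all 10 splits of the 6 arrays into groups of 3 were fitted. Odorant receptors were placed in class I or class II by the MOR family number in their RefSeq synonyms, with families up to 42 in class I. The class difference was also set against all 1001 rotations of the class labels along the genome order of the receptors.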

Results

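Gene expression was measured in cells sorted from the main olfactory epithelium of mouse embryos at E18.5. The targeted Fezf1 allele carries EGFP under the Fezf1 promoter, so green fluorescence marked the cells that use this promoter in heterozygous and in null embryos. Fezf1 is a zinc-finger transcription factor of the olfactory epithelium and forebrain. Total RNA of each sort was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array, with 3 heterozygous and 3 null arrays on a C57BL/6 background. Each array gave 35557 probe-set values, with medians between 5.82 and 5.95 log2 units, and 19938 genes were tested. Differences are given as null minus heterozygous on the log2 scale, and the number of arrays limits their precision.

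The comparison asked how the transcriptome of these cells differs when they lack Fezf1. Fezf1 itself fell from 11.23 ± 0.09 in heterozygous to 5.92 ± 0.36 in null cells (SD, n = 3 each), a difference of -5.31 (SE 0.19, adjusted p = 0.000755). This was a 39.6-fold lower signal, and the 3 null arrays lay between 5.56 and 6.28, close to the median probe set of an array. Its paralogue Fezf2 stood at 5.67 ± 0.20 and 6.00 ± 0.32, a difference of 0.33 (SE 0.19, adjusted p = 0.647). Besides Fezf1, the genes that fell were mostly odorant receptors, the G protein-coupled receptors with which olfactory neurons detect odours, while the genes that rose included the signalling genes Bmp7, Cd200 and Gnai2.

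In all, 110 genes passed an adjusted p of 0.05, 19 of them higher and 91 lower in null cells. Of these, 106 differed at least 2-fold, 16 higher and 90 lower, and 1890 genes had an unadjusted p under 0.05. In all 110 genes the 3 null values lay entirely on one side of the 3 heterozygous values, as they did in 3686 of the 19938 genes, where chance gives 10%. Null replicate 1 stood apart from the other arrays, with correlations across genes of 0.905 to 0.935 to them against 0.975 to 0.995 among the other 5. Without it, 531 genes passed (198 higher, 333 lower), 279 of them at least 2-fold, and all 110 were again called in the same direction. Leaving out another array lowered the count, to 69, 55 and 45 without heterozygous replicates 1, 2 and 3, and to 40 and 51 without null replicates 2 and 3.

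**Figure D1:**
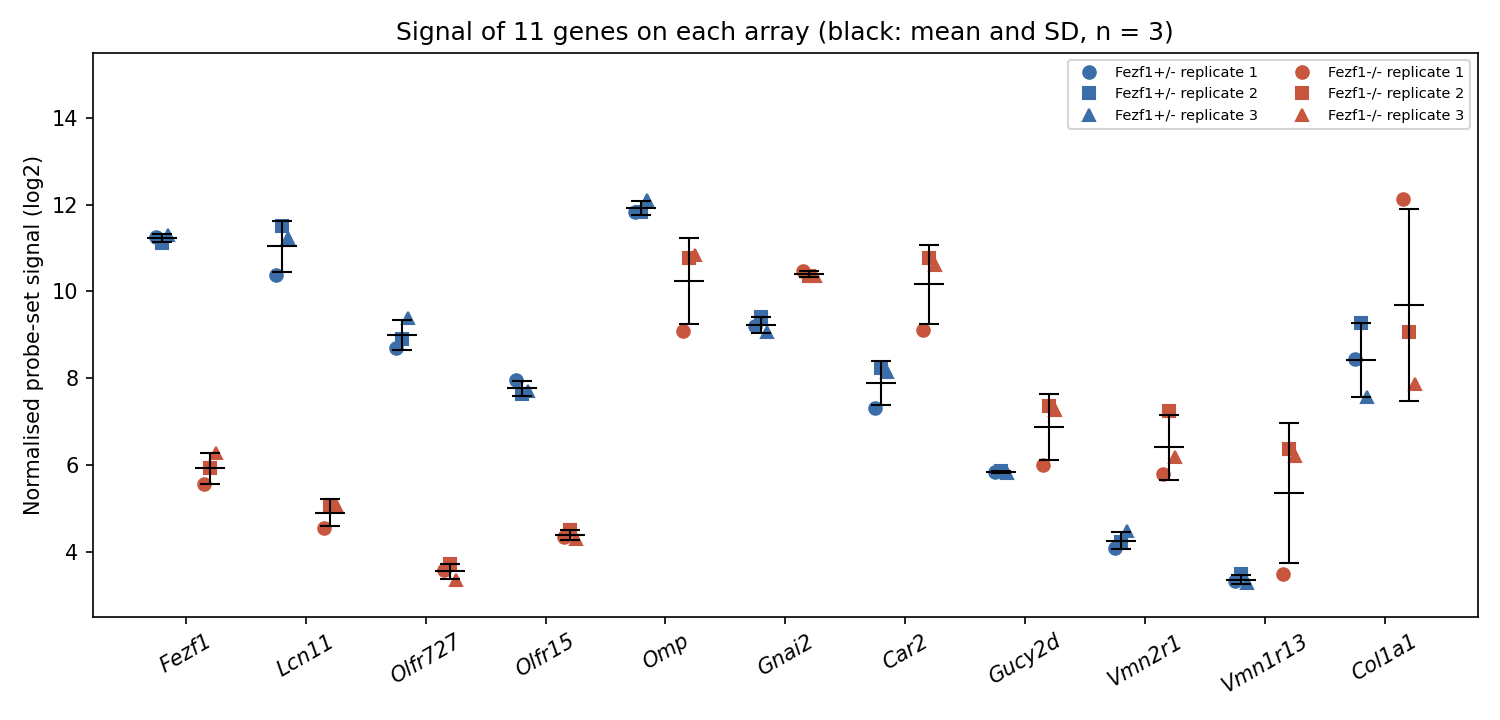
Normalised log2 signal (vertical axis) of 11 genes on each of the 6 arrays, with heterozygous arrays in blue, null arrays in red, a symbol for each replicate number, and black marks for the mean and SD of 3 arrays. Fezf1, Lcn11, Olfr727 and Olfr15 lie lower on every null array, Gnai2 lies higher on every null array (10.40 against 9.23 on average), and Col1a1 reaches 12.1 on null replicate 1.

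Odorant receptors made up 78 of the 91 genes that fell, or 85.7%, and 13 were other genes. In the 5 arrays without null replicate 1 they made up 188 of 333, with 145 other genes, and 7 of 13 when only genes above the median signal were tested. Olfr727 stood between 8.70 and 9.39 on the heterozygous arrays and fell to 3.54 ± 0.18 in null cells (difference -5.45, SE 0.20, adjusted p = 0.000755, n = 3 each). Olfr1208 (-4.28), Olfr731 (-3.91), Olfr1178 (-3.88), Olfr726 (-3.87), Olfr166 (-3.76) and Olfr728 (-3.55) fell as well, and so did Olfr263 (-3.52), Olfr536 (-3.52), Olfr170 (-3.45) and Olfr15 (-3.39). Several of these receptors, Olfr727 included, ended in null cells below the lower quartile of every array (4.30 to 4.44), such as Olfr731 at 3.39 ± 0.14 and Olfr1178 at 3.54 ± 0.12. Signal over background was not examined there, so the size and order of these falls depend on the background estimate and no fold is given.

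Among the 1015 odorant receptors measured, 78 fell and 0 rose by limma, with 449 lower and 0 higher at an unadjusted p under 0.05. Adjusted over the list alone, 335 fell. The receptors that fell had a median difference of -2.51, from -5.45 to -1.15, and odorant receptors were more frequent among the changed genes than among the others (Fisher's exact test, two-sided, odds ratio 49.1, p = 8.69e-76, across genes, which are not independent replicates). Over the whole family 939 receptors had a negative difference and the median was -0.73 (camera adjusted p = 1.48e-58; adjusted p = 0.736 with an estimated correlation). In the 5 arrays without null replicate 1 the median was -0.41, and 270 receptors had a positive difference, against 76 over all arrays. There, 188 receptors fell and 5 rose (373 and 48 adjusted over the list alone), those that rose including Olfr1350 (1.80, SE 0.19), Olfr1396 (1.29, SE 0.24) and Olfr157 (1.01, SE 0.17), which are named here after their values were seen. The count of receptors that fell was 44 and 37 without heterozygous replicates 2 and 3, and 33 and 42 without null replicates 2 and 3.

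**Figure D2:**
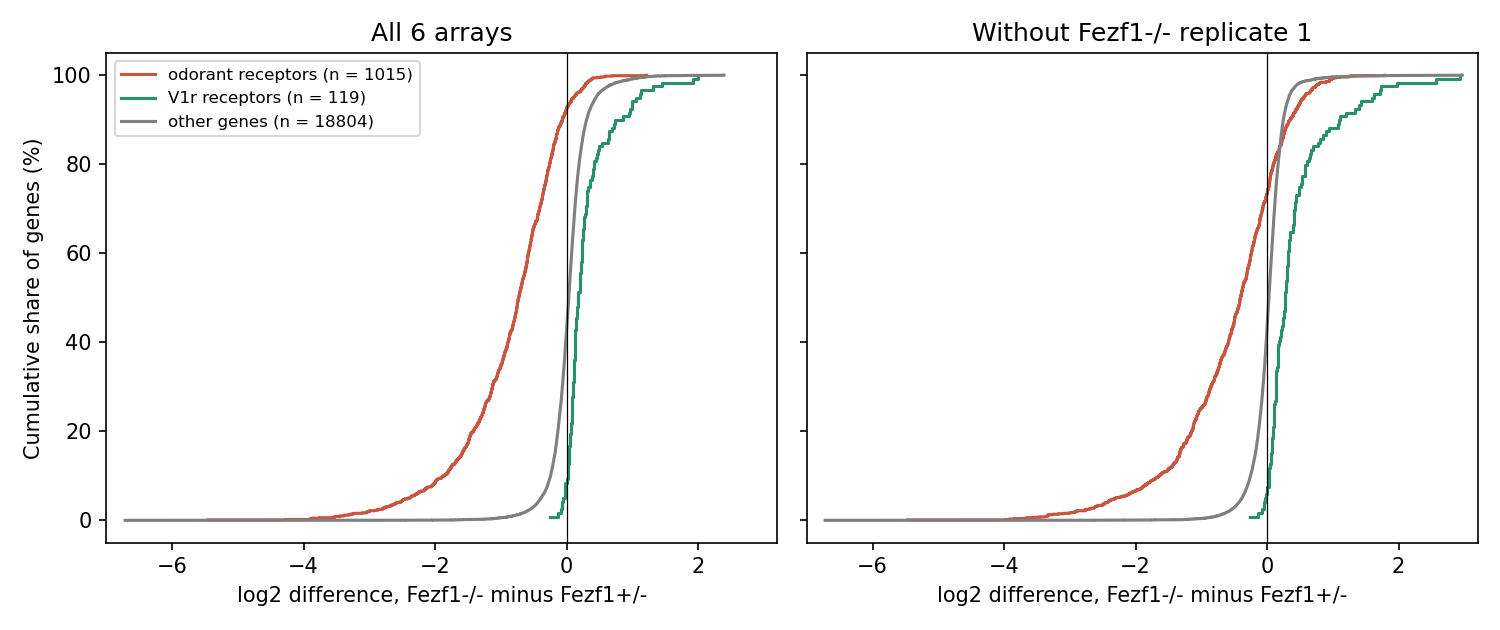
Cumulative share of genes in percent (vertical axis) against the log2 difference, null minus heterozygous (horizontal axis), for 1015 odorant receptors in red, 119 V1r receptors in green and the other genes in grey, over all 6 arrays (left) and without null replicate 1 (right). The odorant receptor curve lies to the left, with a median of -0.73 over all arrays and -0.41 without that array, and the V1r curve lies to the right, with medians of 0.17 and 0.27.

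Apart from receptors, genes with high signal in heterozygous cells fell far. The gene 5430401F13Rik fell from 10.31 ± 0.66 to 3.60 ± 0.16 (difference -6.71, SE 0.33, adjusted p = 0.00198), and as its null values of 3.44 to 3.75 also lay below the lower quartile, the size of this fall depends on the background estimate. BC051076 fell from 11.09 ± 0.68 to 4.76 ± 0.17 (difference -6.34, SE 0.34, adjusted p = 0.00216). Lcn11, a member of the lipocalin family of small carrier proteins, fell from 11.04 ± 0.59 to 4.89 ± 0.31 (difference -6.15, SE 0.32, adjusted p = 0.00216, n = 3 each). These 3 genes and Fezf1 were the only non-receptors among the 15 called genes with the lowest differences. Of those 15 genes, 14 were called whichever single array was left out, the exception being Olfr731, which was not called without heterozygous replicate 2 or without null replicate 2 or 3.

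The 19 genes that rose were fewer than the 91 that fell, but more than the 13 that fell outside the odorant receptors. Without null replicate 1, 198 genes rose, 5 of them odorant receptors, and 145 genes fell outside that family. Over all 6 arrays the largest called rise was 1.82 and the largest called fall -6.71. Rassf9 rose by 1.82 (SE 0.19, adjusted p = 0.0223) and Fkbp9, a peptidyl-prolyl isomerase of the endoplasmic reticulum, by 1.79 (SE 0.19, adjusted p = 0.0219). Cd200, a cell surface glycoprotein, rose from 6.78 ± 0.14 to 8.36 ± 0.06, a 2.98-fold increase (adjusted p = 0.0042), and Bmp7, a secreted bone morphogenetic protein, rose from 7.06 ± 0.03 to 8.28 ± 0.06 (difference 1.22, SE 0.08, adjusted p = 0.0042). Gnai2, the G protein alpha subunit that V1r-expressing vomeronasal neurons use, rose from 9.23 ± 0.18 to 10.40 ± 0.06, a 2.25-fold increase (adjusted p = 0.0201). Adcy2, an adenylate cyclase, rose by 1.51, the zinc-finger gene Zfp521 by 1.44, Pdzrn3 by 1.44, Fam102b by 1.44 and the inositol transporter gene Slc5a3 by 1.36. The mitochondrial carrier gene Slc25a24 rose by 1.30, Mpdz by 1.17, the cell cycle inhibitor Cdkn1b by 1.16, Egfl6 by 1.14 and B3galnt1 by 1.13. Of these 15 genes, only Cd200 and Bmp7 were called whichever array was left out. Of the other 13, Fam102b lost its call only without null replicate 2, and 12 were not called without null replicate 2 or 3, nor without heterozygous replicate 3.

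Over all 6 arrays, markers of mature olfactory sensory neurons were all on the lower side in null cells, although none passed over all genes. The 21 measured markers had a median difference of -1.07 (camera adjusted p = 2.30e-12; adjusted p = 0.736 with an estimated correlation). By limma 0 of them passed, with 12 lower at an unadjusted p under 0.05 and 8 lower adjusted over the list alone. The exchanger gene Slc24a4 differed by -1.07 (SE 0.15, adjusted p = 0.0635) and the phosphodiesterase gene Pde1c by -0.97 (SE 0.15, adjusted p = 0.0694), and Omp, which encodes olfactory marker protein, by -1.69 (SE 0.48, adjusted p = 0.327). With null replicate 1 left out, where mature markers lay a median of -1.42 from the other null arrays, the list median was -0.72 and 6 members fell, 13 adjusted over the list alone. In that fit 2 members had a positive difference, and the adhesion gene Ncam2 (0.36, SE 0.12, adjusted p = 0.207), named here after its value was seen, was higher adjusted over the list alone. There, Omp fell by 1.12 (SE 0.12, adjusted p = 0.00702), as did Kirrel2 (-1.21), Stoml3 (-1.17), Slc24a4 (-1.15) and the adenylate cyclase gene Adcy3 (-0.93). The channel gene Cnga2 differed by -0.49 (SE 0.16, adjusted p = 0.2) and the olfactory G protein gene Gnal by -1.07 (adjusted p = 0.0776) in the same 5 arrays.

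Markers of immature olfactory neurons took another course. Their 19 members had a median of -0.11 over all arrays (camera adjusted p = 0.430) and 0 passed by limma, with 1 higher at an unadjusted p under 0.05. Chl1 differed by 1.15 (SE 0.32, adjusted p = 0.318) and Dcx by -0.57 (SE 0.40, adjusted p = 0.703). With null replicate 1 left out, where this list lay a median of -1.08 from the other null arrays, its median was 0.32 (camera adjusted p = 0.000119; adjusted p = 0.533 with an estimated correlation). In those 5 arrays Stmn4 rose by 0.94, Chl1 by 0.77 and Ablim1 by 0.71. Transcription factors of olfactory neurons had a median of -0.26 over 14 members (camera adjusted p = 0.00477; adjusted p = 0.768 with an estimated correlation), with Ebf4 at -0.82 and Uncx at -0.87, neither past the threshold. Their median without null replicate 1 was -0.05, and Nfix alone fell, by 0.72.

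Genes of the vomeronasal organ, the neighbouring chemosensory epithelium, were examined by receptor family and by neuronal marker. V1r receptors had positive differences in 109 of 119 members, with a median of 0.17 (camera adjusted p = 7.97e-09; adjusted p = 0.768 with an estimated correlation). By limma 0 of them passed, over all genes or adjusted over the list alone, with 16 higher and 0 lower at an unadjusted p under 0.05, and Vmn1r49 (0.86, SE 0.22) and Vmn1r89 (0.95, SE 0.25) had the smallest p-values. The V1r median without null replicate 1 was 0.27 and 12 rose, 25 adjusted over the list alone, among them Vmn1r13 (2.93, SE 0.11, adjusted p = 0.000190), Vmn1r171 (2.57), Vmn1r178 (1.97) and Vmn1r40 (1.74). The heterozygous means of Vmn1r13 (3.36), Vmn1r178 (3.61) and Vmn1r40 (4.01) lay below the lower quartile of every array, so the sizes of their differences depend on the background estimate, while that of Vmn1r171 was 4.93. With null replicate 2 left out instead, the V1r median was 0.07 (camera adjusted p = 0.00168; adjusted p = 0.777 with an estimated correlation). On the single arrays the V1r median lay 0.03, 0.38 and 0.14 above the heterozygous mean in null replicates 1, 2 and 3. The 46 V2r receptors had a median of 0.08 (camera adjusted p = 0.0631), with Vmn2r1 at 2.15 (SE 0.37, adjusted p = 0.111) and Vmn2r14 at 0.45. Vmn2r1 rose by 2.46 without null replicate 1 (SE 0.29, adjusted p = 0.00995), and the V2r median was 0.11 (camera adjusted p = 0.0176; adjusted p = 0.593 with an estimated correlation). The V2r list was also called higher without null replicate 3 (0.11, camera adjusted p = 0.00900; adjusted p = 0.683 with an estimated correlation), while its median without null replicate 2 was 0.0076.

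Of the 14 vomeronasal neuron markers, Gnai2 rose and 13 did not pass, with a list median of 0.11 (camera adjusted p = 0.446). Adjusted over the list alone the count was also 1, and without null replicate 1 it was 5 higher and 1 lower. The 4 formyl peptide receptors had a median of 0.12, with Fpr-rs3 at 0.24 and Fpr-rs6 at 0.18 (camera adjusted p = 0.309), and the 8 H2-M10 family genes a median of 0.20, with H2-M10.3 at 0.28 and H2-M9 at 0.24 (camera adjusted p = 0.0956). Trace amine receptors, the small second family of olfactory receptors, had a median of -0.14 over 12 members (camera adjusted p = 0.274), with Taar8b at -1.24 (SE 0.43, adjusted p = 0.451) and Taar9 at -1.22 (SE 0.43, adjusted p = 0.457). The trace amine median without null replicate 1 was 0.14 and Taar7b rose by 1.46 (SE 0.17, adjusted p = 0.00863).

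Genes of atypical olfactory neurons that use the receptor guanylyl cyclase Gucy2d or Ms4a receptors had a median of 0.81 over 14 members (camera adjusted p = 0.00248; adjusted p = 0.514 with an estimated correlation). None passed over all genes by limma, 4 were higher at an unadjusted p under 0.05, and 2 were higher adjusted over the list alone. Car2, a carbonic anhydrase of Gucy2d neurons, differed by 2.27 (SE 0.50, adjusted p = 0.197) and the phosphodiesterase Pde2a by 1.76 (SE 0.39, adjusted p = 0.202). Several Ms4a members, a family that macrophages also express, were high on null replicate 1, with Ms4a6c at 8.86 there against 5.17 and 5.16 on the other null arrays. With that array left out the median was 0.11, and Car2 (2.79, SE 0.27, adjusted p = 0.00443), Pde2a (2.22, SE 0.10, adjusted p = 0.000249) and Gucy2d (1.48, SE 0.09, adjusted p = 0.000716) rose.

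Markers of cell types outside the neuronal lineage lay highest on null replicate 1. Relative to the mean of the other null arrays, the median shift on it was 3.61 for mesenchyme and bone, 1.95 for myeloid cells, 1.95 for ensheathing glia, 1.41 for sustentacular cells and 1.23 for endothelium. Col1a1, a collagen gene of mesenchyme, stood at 12.1 on that array and between 7.57 and 9.28 on the other 5. Over all arrays the medians were 0.95 for mesenchyme and bone (14 members, camera adjusted p = 0.0129; adjusted p = 0.768 with an estimated correlation), 0.80 for myeloid cells (14 members, camera adjusted p = 0.0035; adjusted p = 0.768 with an estimated correlation) and 0.44 for ensheathing glia (9 members, camera adjusted p = 0.0289; adjusted p = 0.768 with an estimated correlation). No member of these lists passed by limma, and 0 had an unadjusted p under 0.05. Sp7 (0.51), Col2a1 (0.54), S100a9 (0.83), Cd68 (0.86), Ngfr (0.31) and S100b (0.88) had the smallest p-values in them. The 3 medians without null replicate 1 were -0.01, 0.10 and 0.11. Endothelial markers had a median of 0.33 over 10 members (camera adjusted p = 0.138), with Cldn5 at 0.66 and Flt1 at 0.39, and the 4 erythroid markers a median of 0.17 (camera adjusted p = 0.802), with Hbb-y at -0.23 and Alas2 at 5.49 ± 0.66 and 6.99 ± 2.47 in heterozygous and null cells.

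**Figure D3:**
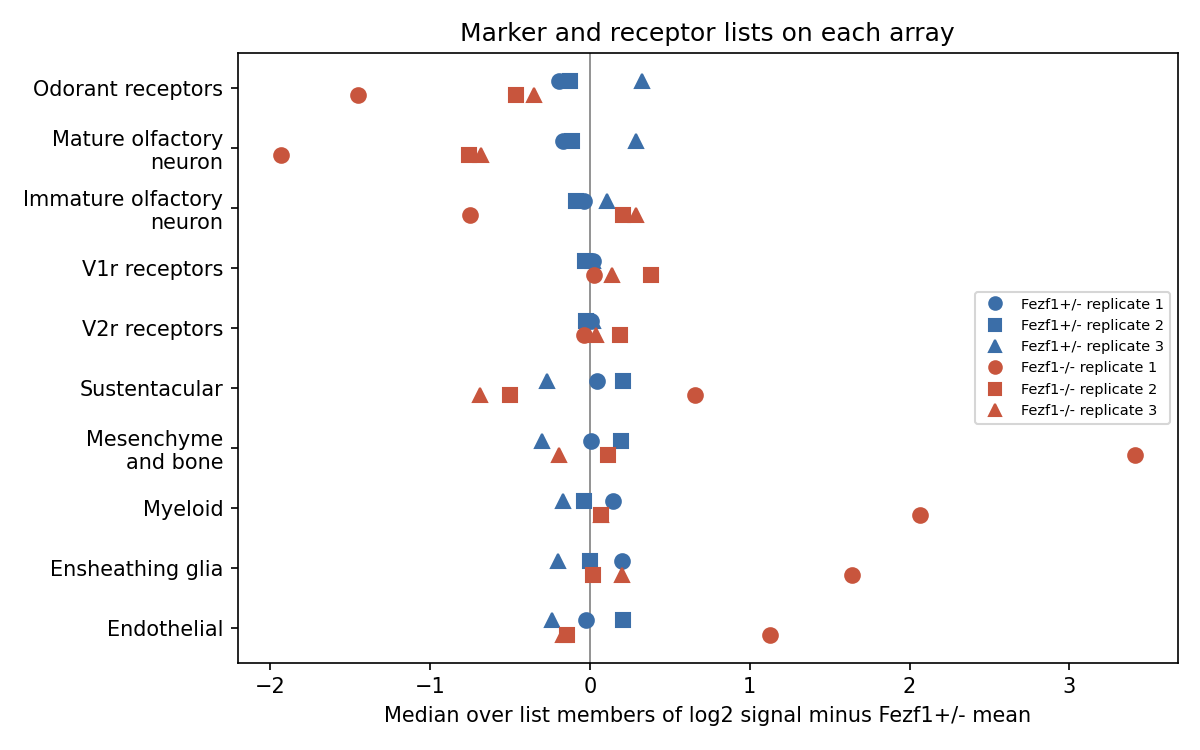
Median over the members of 10 gene lists of log2 signal minus the heterozygous mean (horizontal axis), 1 point per array, with heterozygous arrays in blue and null arrays in red. Null replicate 1 reaches 3.41 for mesenchyme and bone and -1.93 for mature olfactory neurons, where null replicates 2 and 3 lie at 0.12 and -0.19 and at -0.76 and -0.68.

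Supporting and basal cells of the epithelium showed no called member over all arrays by limma, and at an unadjusted p under 0.05 stood 1 higher gene in each of the sustentacular, microvillar, progenitor and Notch lists and 0 in the others. Sustentacular markers had a median of -0.08 (15 members, camera adjusted p = 0.506), with Krt8 at 0.67 and Sec14l3 at -0.56. This median was -0.58 without null replicate 1 (camera adjusted p = 1.83e-06; adjusted p = 0.533 with an estimated correlation), Ermn fell by 0.96, and 7 members were lower and 1 higher adjusted over the list alone. Bowman gland markers had medians of -0.18 (11 members, camera adjusted p = 0.191) and, without null replicate 1, -0.54, with Obp2a at -1.03 and Kcnn4 at -0.37 over all arrays. Microvillar and tuft cell markers had a median of 0.07 (12 members, camera adjusted p = 0.474), with Trpm5 at 0.43 and Avil at 0.27. Horizontal basal cell markers had a median of 0.14 (9 members, camera adjusted p = 0.274), with Krt15 at 0.78 and Icam1 at 0.48. Neurogenic progenitor genes had a median of 0.10 (16 members, camera adjusted p = 0.577), with Eya2 at 0.67 and Hes6 at -0.25, and without null replicate 1 Eya2 rose by 0.96. For the 28 cell cycle genes the median was 0.01, the mean -0.005 and the direction of the test downward (camera adjusted p = 0.617), with Ube2c at -0.15 and Rrm1 at 0.16. The cell cycle median without null replicate 1 was -0.18, with 2 of 28 members positive (camera adjusted p = 0.000425; adjusted p = 0.593 with an estimated correlation). Notch pathway genes had a median of 0.19 (17 members, camera adjusted p = 0.139), with Dll1 at 0.51 and Heyl at 0.49, and without null replicate 1 Jag1 fell by 0.81.

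Genes of cilia lay on the lower side. Motile cilia genes had a median of -0.51 (14 members, camera adjusted p = 5.11e-06; adjusted p = 0.736 with an estimated correlation), with Rsph4a at 8.11 ± 0.33 in heterozygous and 6.92 ± 0.69 in null cells and Dnaic1 at -0.37, and primary cilia genes a median of -0.39 (17 members, camera adjusted p = 8.74e-06; adjusted p = 0.768 with an estimated correlation), with Bbs5 at -0.68 and Ift20 at -0.30. Axon guidance genes had a median of -0.34 (25 members, camera adjusted p = 0.00786; adjusted p = 0.768 with an estimated correlation), with Kirrel2 at -1.67 (SE 0.40, adjusted p = 0.233) and Plxna4 at -1.10 (SE 0.27, adjusted p = 0.241). The medians of these 3 lists without null replicate 1 were -0.30, -0.13 and -0.16, and Kirrel2 (-1.21) and Plxna4 (-0.80) fell. Synaptic genes had a median of -0.32 (14 members, camera adjusted p = 0.0679), with Syn2 at 0.78 and Rims1 at -0.38. The synaptic median was 0.05 without null replicate 1, where the test pointed upward (camera adjusted p = 0.367), and camera called the list lower without null replicate 2 (adjusted p = 0.00462; adjusted p = 0.8 with an estimated correlation) or 3 (adjusted p = 0.0053; adjusted p = 0.683 with an estimated correlation). By limma 0 members of these 4 lists passed over all arrays, with 3, 2, 4 and 0 lower and 0, 0, 1 and 1 higher at an unadjusted p under 0.05. Forebrain genes had a median of 0.01 (11 members, camera adjusted p = 0.610), with Emx1 at 0.66 and Eomes at -0.23. Genes of migratory neurons that include those of the gonadotropin-releasing hormone lineage had a median of 0.23 (9 members, camera adjusted p = 0.474), with Gal at 0.65 and Chrna3 at 0.74. Emx1 rose by 0.84, Gal by 0.88 and Chrna3 by 1.13 without null replicate 1.

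Stress, death and housekeeping lists had no member past the threshold over all genes by limma. At an unadjusted p under 0.05 stood 1 lower stress response gene, 2 higher apoptosis genes, 2 higher ribosomal protein genes and 4 lower oxidative phosphorylation genes. Integrated stress response genes had a median of -0.14 (15 members, camera adjusted p = 0.0631), with Herpud1 at -0.49 and Ddit3 at -0.60. This list was called lower without null replicate 2 (median -0.30, camera adjusted p = 0.0105), null replicate 3 (-0.14, 0.0369) or heterozygous replicate 2 (-0.20, 0.0306), and the adjusted p with an estimated correlation was 0.777, 0.683 and 0.744 there. Immediate early genes had a median of 0.13 (15 members, camera adjusted p = 0.370), with Egr2 at 0.46 and Klf2 at 0.37. On null replicate 1 the immediate early genes lay a median of 1.37 above the other null arrays. Their list median was -0.22 without null replicate 1 (camera adjusted p = 0.000418, and 0.593 with an estimated correlation). Without null replicate 3 it was 0.38 (camera adjusted p = 0.00836, and 0.714 with an estimated correlation). Apoptosis and p53 genes had a median of 0.17 (13 members, camera adjusted p = 0.00477; adjusted p = 0.514 with an estimated correlation), with Aen at 0.46 and Pmaip1 at 0.49. Ribosomal protein genes had a median of 0.08 (49 members, camera adjusted p = 0.0409; adjusted p = 0.768 with an estimated correlation), with Rpl26 at 0.46 and Rps14 at 0.29, and oxidative phosphorylation genes a median of -0.16 (62 members, camera adjusted p = 7.97e-09; adjusted p = 0.768 with an estimated correlation), with Ndufc1 at -0.37 and Uqcrc1 at -0.33. The oxidative phosphorylation median without null replicate 1 was -0.096 (camera adjusted p = 0.000457; adjusted p = 0.693 with an estimated correlation). The 4 sex-linked genes had a median of -1.10 (camera adjusted p = 0.310), and without heterozygous replicate 2 the median was -1.95 and the list was called lower (camera adjusted p = 0.0132; adjusted p = 0.744 with an estimated correlation). Xist, expressed from the inactive X chromosome of females, stood at 4.67 in heterozygous replicate 3 and between 8.90 and 10.23 on the other arrays. Y-linked Eif2s3y stood at 8.54 in that replicate, 7.94 in heterozygous replicate 1 and between 4.68 and 6.48 on the others. Y-linked Uty stood at 7.37 and 7.93 in heterozygous replicates 1 and 3 and between 3.95 and 5.85 on the others. Kdm5d, also Y-linked, stood at 6.78 and 6.65 there and between 4.66 and 5.52 on the others. Heterozygous replicate 1 thus held both Xist and high Y-linked signal. Sex-linked signal was not balanced between the genotypes, and no fit adjusted for sex. Eif2s3y differed by -1.57 (SE 0.87) and Xist by 2.01 (SE 1.37), neither past the threshold.

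Over the 35 lists large enough to test, camera with its preset correlation called 14, 7 in each direction. With an estimated correlation 0 were called, 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.514. These correlations were estimated from 6 arrays, null replicate 1 among them. They ran from -0.064 for atypical neurons to 0.963 for immediate early genes, with 0.559 for odorant receptors. The power of this test was not examined, so its high p-values do not show that a list stayed unchanged. With fry 0 were called and 4 had an unadjusted p under 0.05. The mixed form of fry, which asks for no shared direction, called odorant receptors (adjusted p = 0.00877) and H2-M10 genes (adjusted p = 0.00403). In the 5 arrays without null replicate 1, camera called 15 lists, 0 with an estimated correlation, and fry called 3, those of atypical neurons (adjusted p = 0.0052), migratory neurons (adjusted p = 0.0181) and H2-M10 genes (adjusted p = 0.04). Without null replicate 1, camera no longer called the lists of mesenchyme, myeloid cells, ensheathing glia, olfactory transcription factors, axon guidance and ribosomal proteins. The mesenchyme and ribosomal calls were also lost without heterozygous replicate 1 or 3, and the glial call without heterozygous replicate 3. Medians of called lists lay further from 0 in other fits, at -0.44 and -0.42 for olfactory transcription factors without null replicates 2 and 3, 1.55 for mesenchyme without null replicate 3, and 0.73 for ensheathing glia and 0.12 for ribosomal proteins without null replicate 2. Some lists that camera with its preset correlation did not call over all arrays were called when 1 array was left out. Neurogenic progenitor genes (median 0.18, adjusted p = 0.0183) and Bowman gland markers (-0.54, adjusted p = 0.000280) were called without null replicate 1 (both adjusted p = 0.533 with an estimated correlation), and immature neuron markers (-0.27, adjusted p = 0.0411; adjusted p = 0.723 with an estimated correlation) without null replicate 3. Horizontal basal cell markers (0.27, adjusted p = 0.0488; adjusted p = 0.744 with an estimated correlation) were called without heterozygous replicate 2, and trace amine receptors (-0.39, adjusted p = 0.0334) and cell cycle genes (-0.065, adjusted p = 0.0294) without heterozygous replicate 1 (both adjusted p = 0.835 with an estimated correlation). Notch genes and endothelial markers were called higher without null replicate 2 (0.37 and 0.49), null replicate 3 (0.32 and 0.53) or heterozygous replicate 2 (0.28 and 0.43), where the adjusted p with an estimated correlation was 0.8, 0.683 and 0.744 for both lists. The planned test with an estimated correlation was also run, after the data were seen, in the 6 fits that left out 1 array, where 0 lists were called, at most 2 had an unadjusted p under 0.05, and the lowest adjusted p was 0.533. Adjusted over the list alone, members passed in the lists of mature neurons, vomeronasal neurons, odorant receptors and atypical neurons and for Fezf1, and in none of the others. In the fit without null replicate 1 they also passed among immature neuron (4 higher), progenitor (5 higher, 1 lower), olfactory transcription factor (3 lower), Bowman gland (4 lower), microvillar (2 lower), Notch (1 higher, 2 lower) and axon guidance genes (1 higher, 3 lower). There, 1 lower gene passed in each of the primary cilia, mesenchyme and endothelial lists, 1 higher in each of the synaptic, stress response, forebrain, trace amine and V2r lists, and 2 higher in that of migratory neurons. V1r receptors (25 higher), sustentacular markers (1 higher, 7 lower) and Fezf2 (higher) passed in that fit as well.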

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

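The tests of other cell types and of a heterozygous sample as the source of null replicate 1 were chosen only after that array had been seen to stand apart, and the other tests in this part before their results were seen.

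Probe sets outside the tested genes also differed. Of 12147 probe sets without a listed gene, 2 passed an adjusted p of 0.05, both lower in null cells, and 665 had an unadjusted p under 0.05. Without null replicate 1 the count was 28, with 25 higher. Of 1621 probe sets with several gene symbols, 16 passed, all lower, and 136 had an unadjusted p under 0.05. Without null replicate 1 the count was 39, with 12 higher and 27 lower. These probe sets draw attention because no comparison of named genes used them.

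Null replicate 1 took 82.6 on a first principal component that held 65.4% of the variance, against -38.1 to -7.02 for the other arrays. A different label is argued against, since its Fezf1 signal lay 5.57 log2 units below the lowest heterozygous array. An array-wide scaling or compression of signal is also argued against, since after removal of the trend with signal level the mesenchyme and mature neuron lists still lay 4.90 apart on it. Cells of mesenchyme, glia, blood or vessels that passed the sort for EGFP may be the source, since the mesenchyme list lay 3.61 above the other null arrays with 14 of 14 members higher, and the abundant transcripts Col1a1 and Fabp7 reached 12.1 and 11.9. Whether the embryo, the dissection or the gate brought such cells stays open, and no biological explanation was tested.

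With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For genes changed, the real split gave 110 and the highest other 0, so that 1 split of the 10 reached the real value. For changes of at least 2-fold the values were 106 and 0 (1 split), and for odorant receptors called one way 78 and 0 (1 split). Genes at an unadjusted p under 0.05 numbered 1890 in the real split and up to 1511 in another, the one that parts heterozygous replicates 1 and 2 and null replicate 1 from the rest. For gene lists called by camera the real split gave 14 and the highest other 28, and 8 of the 10 splits gave at least as many, which points to a structure of these arrays that camera's preset correlation does not absorb.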

How the results depend on the processing

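All alternatives in this part were planned. Quantile normalisation, centring, averaging of probe sets and robust eBayes called 106, 101, 108 and 109 genes. A floor of 4 lay below every value, so it tested nothing and is left out of the counts below. The filter on genes above the median mean tested 33 of the 110 called genes, and 24 of these stayed called. It gave 24 changed, 11 higher, 13 lower, 23 at least 2-fold, 7 odorant receptors lower and 9 lists. Array weights gave 740, 284, 456, 331 and 255 for the first 5 of these, with a weight of 0.136 for null replicate 1. The unmoderated per-gene test gave 8, 2, 6, 7 and 5. Leaving out single arrays gave 40 to 531 changed, 2 to 198 higher, 38 to 333 lower, 40 to 279 at least 2-fold and 33 to 188 odorant receptors lower, where the highest values came without null replicate 1. List calls numbered 0 with an estimated correlation and 0 with fry for a shared direction. The replicate block gave 88 changed, 62 of them among the 110, with 5 higher. Same-numbered arrays deviated from their group means with r of 0.225, -0.332 and 0.541, and 3 of 6 arrays correlated best with their own number. Null replicate 1 dominates the deviations of the null group, so this check cannot decide whether the numbers paired the arrays.

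Fezf1 was called in the same direction throughout. Over 96 named genes, 1159 of 1301 values kept direction and side of the threshold, 103 lost the call, 35 gained it and 4 changed sign. The sign changes were those of Egr2 (-0.027) and Klf2 (-0.021) with array weights and without null replicate 1, and over left-out arrays these genes ranged from -0.010 to 0.70 and from -0.044 to 0.60. Over 35 lists, 396 of 480 values were the same, 16 weaker, 31 stronger and 37 opposite in direction of test, so that a printed median can keep its sign. Opposite medians with array weights were -0.13 for endothelial, 0.014 for erythroid, -0.11 for horizontal basal, 0.29 for immature neuron, -0.21 for immediate early, 0.038 for mesenchyme, -0.0076 for microvillar, -0.052 for Notch, -0.032 for ribosomal, 0.038 for synaptic and 0.072 for trace amine lists. With the filter they were 0.0042 for cell cycle, -0.30 for migratory neuron, -0.076 for sustentacular and 0.46 for trace amine lists, and with quantile normalisation 0.032 for cell cycle. Over left-out arrays such lists ranged from -0.27 to 0.32 (immature neuron), -0.045 to 0.24 (vomeronasal), -0.068 to 0.31 (horizontal basal), -0.18 to 0.095 (cell cycle), -0.045 to 0.37 (Notch), -0.58 to 0.12 (sustentacular), 0.0028 to 0.17 (microvillar), -0.43 to 0.052 (synaptic), -0.051 to 0.090 (forebrain), -0.011 to 1.55 (mesenchyme), -0.033 to 0.34 (erythroid), -0.14 to 0.53 (endothelial), -0.22 to 0.38 (immediate early), -0.39 to 0.14 (trace amine) and -0.021 to 0.12 (ribosomal). The cause of these changes was not tested.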

Other observations

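The comparison of receptor classes, by both of its tests, and the test of vomeronasal tissue were chosen only after results had been seen, as were the genes named below from the 5 arrays without null replicate 1, and the other tests were chosen before.

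In those 5 arrays a group of genes outside the receptor families rose in null cells. Sphkap, an anchoring protein of protein kinase A, rose by 2.97 (SE 0.23, adjusted p = 0.00192), the phosphodiesterase gene Pde1a by 2.63, B3galt1 by 2.55, Vav3 by 2.40 and the potassium channel gene Kcnj5 by 2.32. Gmnc, a regulator of multiciliated cell fate, rose by 2.15 (SE 0.19, adjusted p = 0.00325), the homeobox gene Dlx3 by 2.09 and Trp73 by 1.59, while motile cilia genes had a median of -0.30. Sult6b1 and Fam163a rose by 2.13 and 2.05. In all 6 arrays the same differences were smaller and not past the threshold, such as 2.39 for Sphkap (adjusted p = 0.189) and 1.81 for Gmnc (adjusted p = 0.124).

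Several genes with high signal in heterozygous cells fell in the same 5 arrays. Wfdc18 fell by 2.63 (SE 0.21, adjusted p = 0.00221), and so did the secretoglobin gene Scgb1c1 (-1.45), the metallothionein genes Mt2 (-1.05) and Mt1 (-0.81) and the glutathione transferase gene Gstm1 (-0.88). On null replicate 1 Wfdc18 stood at 10.30 and Scgb1c1 at 10.15, above their heterozygous means of 9.94 and 9.38, so these falls rest on null replicates 2 and 3. Csn3 (-2.27), Car6 (-2.74), Scgb2b27 (-2.46) and Scgn (-1.79), in contrast, fell over all 6 arrays.

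The fall of odorant receptors could reflect a lower share of mature neurons among the sorted cells, as Omp also fell without null replicate 1. The 507 receptors above the median receptor level were examined without null replicate 1. Their differences varied around their trend 3.32 times as widely as replicate error allows (bootstrap 2.97 to 3.68, treating receptors as independent). The falls were thus uneven, but background and shared binding between receptors can also make an equal dilution look uneven. By itself this spread therefore cannot tell dilution from a change that differs between receptors. As a count outside the planned test, 120 called receptors fell further than the lowest mature neuron marker (-1.28) in these 5 arrays. Omp differed by -1.12 there, and 5 receptors rose. For these receptors the values argue against an equal dilution as the only source. They do not argue against a dilution that adds to the falls. A drift of all genes of the receptors' signal level is argued against. Over all 6 arrays 0% of 10000 level-matched lists had a median as low as that of the receptors (random medians 0.06 to 0.09). Such lists treat genes as independent. A change that differs between receptors, whether through choice of receptor or loss of particular neurons, remains a hypothesis on top of any dilution.

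Receptor differences were compared by class and by position. Without null replicate 1 the 117 class I receptors had a median of -0.81 and the 884 class II receptors -0.34, a level-adjusted difference of -0.48, and over all 6 arrays it was -0.37. Shuffling the class over receptors gave a permutation p of 0.0001, the smallest that 10000 permutations can give, but this treats receptors as independent and is too small a p, since the 117 class I receptors form 5 runs in genome order and neighbours differed alike. With the class labels rotated along the genome order, which keeps neighbours together, p was 0.0619 over 1001 rotations, and 2 null arrays entered, so class cannot be told apart from position. The share of receptors called did not follow this order: 3 of 117 class I and 74 of 884 class II receptors were called over all arrays, and 21 and 164 without null replicate 1. Level-adjusted differences of neighbouring receptors correlated at 0.359 over 998 pairs, against an upper bound of 0.146 for shuffles within chromosomes, across genes, which are not independent. Among 408 adjacent pairs of different MOR families, which are less alike in sequence, the correlation was 0.242 against an upper bound of 0.179 (permutation p = 0.0006).

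The higher V1r medians may have more than one source. A drift of low signals is argued against, since 100% of 10000 level-matched lists had a lower median (random medians 0.02 to 0.07). Such lists treat genes as independent, so this share is too extreme. Vomeronasal tissue carried into the dissection cannot be told apart from a change within the epithelium: without null replicate 1 the V2r median of 0.106 was positive but under the share of the V1r median, 0.272, that carried tissue was taken to need. The V2r median lay above 99.91% of 10000 level-matched lists drawn in the same way (random medians 0.0026 to 0.086). Camera called the V2r list higher there (adjusted p = 0.0176, and 0.593 with an estimated correlation). Both go with such tissue, but as well with a change within the epithelium, so they cannot tell these apart. They also treat genes as independent, or nearly so. The 14 vomeronasal neuron markers had a median of 0.24 without null replicate 1 (camera adjusted p = 0.0501, and 0.533 with an estimated correlation). On null replicates 1, 2 and 3 the V2r median lay at -0.04, 0.19 and 0.04 from the heterozygous mean, so the rise was largest on null replicate 2. The tissue origin of these transcripts was not tested.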
